A study of Mus musculus with 2 samples.

How the data were processed

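Splenic CD8 T cells of mice given DHEA in sesame oil or the oil alone were profiled by droplet single-cell RNA sequencing, 1 library per group. Per the labels' protocols, spleens were dissociated, red cells were lysed and CD8 T cells were isolated with magnetic beads. The libraries were made with 10x Genomics 3' chemistry and sequenced on an Illumina NextSeq. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors with Cell Ranger 8.0.1 per the file headers. The submitters' processing notes also name Seurat 4.3.0 and the mm39 genome without saying what each was used for. The number of animals per library and any filter on barcodes are not given in the sources used here. The series' design text calls the isolated cells pooled, without saying from how many animals, so a library may stand for several animals. The 2 libraries have 51 barcodes in common, which were kept.

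The matrices hold 33696 genes. The CTRL matrix has 9495 barcodes and 51638782 UMIs and the DHEA matrix 12128 barcodes and 53020893 UMIs. Barcodes were kept with at least 200 detected genes and under 10% mitochondrial UMIs. That removed 3 and 4 barcodes for too few genes, which were also over the mitochondrial limit, and a further 282 and 453 for mitochondrial share alone, leaving 9210 CTRL and 11671 DHEA cells with median depths of 5530.5 and 4224 UMIs. Scrublet, run per library, marked 1 CTRL and 0 DHEA cells, below the 0.5% at which it would be taken to have worked, so no doublets were removed. An alternative left out the cells with the highest doublet scores at 0.8% per 1000 cells.

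Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen, leaving out immunoglobulin, T cell receptor segment, mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes. Genes were centred and scaled within each library, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 gave 15 clusters. Tools were Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors only. Clusters were named from 23 marker lists. Among their 10 leading genes, naive-like clusters 1 (1629 CTRL and 1533 DHEA cells) and 9 (386 and 314) had 0 naive markers. The naive-like shares depend on these names. The names were assigned after the clusters' leading genes were seen, and 3 clusters (6, 13 and 14) were kept out of the CD8 T-like class on that basis. As an addition chosen after seeing the data, the cells were clustered again without 291 genes of the marker lists and of the lists of T cell states, interferon responses and immediate early genes, giving 16 clusters. Heat shock genes that are in none of these lists stayed in. Each of these took the class that most of its cells had in the clustering with all genes, as did the clusters of every other alternative. The shares of states are given from the clustering without marker genes.

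UMIs were summed over the cells of each library within all CD8 T-like cells (49850459 CTRL and 50437752 DHEA), within naive-like cells (25372018 and 19370890) and within antigen-experienced cells (10245379 and 16013251). Sums were expressed as CPM (UMIs per 1000000 UMIs) of the summed total, and genes with at least 200 UMIs over both libraries were measured. With 1 library per group no test was run. Log2 ratios of DHEA over CTRL carry exact 95% intervals from the split of the 2 counts, CPM exact Poisson intervals and shares exact Clopper-Pearson intervals, all covering counting error only. Where a library had 0 UMIs it was put at 3 UMIs, and no ratio was given where both libraries had 3 or fewer. Genes at least 1.5-fold apart were counted as a rule of size.

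The median log2 ratio of each of 28 gene lists was set against 10000 random lists of the same size matched on mean expression in 20 bins, where at least 3 members were measured. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs and leaving out shallower cells. The shares of Klrg1, Hspa1a, Hspa1b and Eps8l1 were added after the data were seen.

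Named genes were the 8 highest and 8 lowest log2 ratios in CD8 T-like cells, 5 and 5 in each subset, up to 4 members of each list with the largest absolute ratio, and a fixed panel of 24 genes, some of which are not reported here. Immunoglobulin genes, receptor segments, haemoglobin, mitochondrial and ribosomal protein genes and unnamed transcripts were left out of the highest and lowest. Genes that lead a cluster, the nuclear transcripts and the markers of other cell types in the closing part, such as Lyz2 and Klre1, fall outside this rule and were picked after their values were seen. The groups, comparisons, filters, lists, markers, named-gene rule and the alternatives not named as added were fixed before the data were examined.

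The gene and list steps were tested on simulated counts. For CD8 T-like cells (10496 genes), 66 of 66 genes simulated at 1.5-fold had the right direction and 30 were at least 1.5-fold apart. All 65 genes simulated at 2-fold and all 65 at 4-fold were at least 1.5-fold apart, and 4 unchanged genes were. Lists of 20 genes were set against 1000 random lists. With 0.3 added to their log2 ratios they lay outside the central 95% in 100 of 100 cases, and unshifted in 3 of 100. Each gene's counts were drawn independently, so genes that vary together and UMIs gathered in few cells were not simulated. These values check the steps and give no error rate for the results. In antigen-experienced cells the intervals held the true ratio for 95.2% of unchanged genes. For genes simulated at 1.5-fold, 2-fold and 4-fold it was 96.8%, 89.1% and 88.9%.

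Alternatives changed the mitochondrial limit to 5%, the gene minimum to 500, the Leiden resolution to 0.5 or 1.5, the centring, the scaling (median of ratios, TMM, totals without some gene classes), the UMI minimum to 50 or 1000, the fold to 2 and the thinning, and replaced the clusters by a gate on Cd8 and Cd3 UMIs. Added ones counted cluster 6, cluster 13 or cluster 2 in a class, left out the effector-like cluster (there the 8 highest genes are given whatever their UMIs), or subtracted the median log2 ratio of genes of like genomic span. Spans came from GENCODE M21 by gene identifier (10283 of 10528 genes). That annotation is of another genome build than mm39, so it was used for span alone and no coordinates are given.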

Results

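The series measured single-cell transcriptomes of splenic CD8 T cells, the cytotoxic lineage of T lymphocytes, from C57BL/6 mice. The DHEA group received dehydroepiandrosterone (DHEA), an androgen precursor whose repeated injection gives a mouse model of polycystic ovary syndrome, at 40 mg/kg in 20 µL sesame oil daily for 21 days. The other group (CTRL) received the oil vehicle. Each group has 1 library, and the number of animals behind each library is not given in the sources used here. The 2 libraries held 9495 barcodes with 51638782 UMIs (CTRL) and 12128 barcodes with 53020893 UMIs (DHEA). The median per barcode was 5430 UMIs in CTRL and 4049 in DHEA. With 1 library per group no difference given here has a replicate check. All intervals are exact 95% intervals and cover counting error only.

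After filtering, 9210 CTRL and 11671 DHEA cells remained, and CD8 T-like clusters held 8809 (95.6%, 95.2 to 96.1) and 10901 (93.4%, 92.9 to 93.8) of them. Cd8a, the alpha chain of the CD8 co-receptor, stood at 342 CPM in CTRL and 410 in DHEA, and its partner Cd8b1 was also higher in the DHEA library (log2 ratio 0.32). Cd3e, a chain of the T cell receptor complex, differed by 0.09. The helper T cell co-receptor Cd4 had 6 UMIs in CTRL and 2 in DHEA within the CD8 T-like cells. Cluster 6, with few ribosomal protein UMIs and led by Lars2, Gphn and Camk1d, was left outside the class and held 3.08% (2.74 to 3.46) of CTRL and 5.03% (4.64 to 5.44) of DHEA cells. Cluster 13, led by markers of several cell types including Lyz2, Klrb1c and Zbtb16, held 1.17% (0.963 to 1.41) and 1.42% (1.22 to 1.65). Cluster 14, led by Car1 and Angpt1, held 0.0977% and 0.146%.

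The first comparison asked how the CD8 T cells of the 2 libraries were divided among states. Naive-like cells, which carry the lymph node homing gene Ccr7, made up 65.1% (64.1 to 66.1) of CD8 T-like cells in CTRL and 57.3% (56.4 to 58.2) in DHEA, when clustered without marker genes. Memory-like cells, which carry Cxcr3, Il2rb and Ly6c2, made up 13.996% (13.3 to 14.7) and 20.5% (19.7 to 21.3). Effector-like cells, with granule proteases and S100 proteins, made up 1.94% (1.66 to 2.25) and 3.72% (3.37 to 4.09), which is 172 and 409 cells. The class differed in content: 44 of these CTRL cells and 274 of these DHEA cells had a UMI of Gzma, Gzmb, Gzmk or Klrg1. In the clustering with all genes, proliferation genes (Pclaf, Ube2c, Stmn1) also led it, and the proliferation marker Mki67 stood at 155 CPM in its CTRL cells and 107 in its DHEA cells. Memory-like and effector-like cells together are called antigen-experienced here. The name is a label from their genes, and whether these cells had met antigen was not measured. They were 15.9% of CTRL and 24.2% of DHEA cells, a difference of 8.28 percentage points (7.17 to 9.39). With all genes that difference was 11.4 points, but 5.58 at resolution 0.5 and 15.4 without centring per library. In these same 3 settings the memory-like difference was 9.06, 3.27 and 12.7 points and the naive-like difference -9.57, -3.51 and -13.5.

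Innate-like cells, with natural killer receptor genes, made up 3.29% of CTRL and 2.37% of DHEA CD8 T-like cells in the same clustering, and 4.13% and 3.88% in that with all genes, where the difference was -0.252 percentage points (-0.814 to 0.304). Interferon-responding cells were 0.350% and 0.145% (31 and 16 cells), and 3.18% and 1.70% (280 and 185 cells) with all genes, a clustering that uses the class's own markers. A cluster led by Hspa1b, Hspa1a and Ccr9 in the clustering with all genes, cluster 2, stayed unnamed and held 12.5% and 14.1%. Its leading heat shock genes differ between the libraries and stayed in the clustering, so its size is not compared. With all genes and cluster 2 counted as naive-like, the naive-like difference was -8.98 percentage points, against -9.57 without it. Cluster 11, led by Hdac9 and Myb, held 2.80% and 1.87%, and 1.99% and 1.72% with all genes (difference -0.262 points, -0.654 to 0.122). With the marker genes included, naive-like cells were 56.6% and 47.0%, and antigen-experienced cells 16.8% and 28.2%. That clustering also gave an early-activated class, led by Egr3, Tnfrsf9 and Egr2, with 1.71% of CTRL and 1.31% of DHEA cells, for which no share free of its own markers was obtained. Median UMIs per naive-like cell were 5263 in CTRL and 3227 in DHEA, so these shares can also reflect the depth gap and the bead isolation. Of the naive-like clusters, cluster 9 was led by genes of the inflammatory NF-kB pathway (Nfkbia, Nfkb2, Relb, Bcl3, Icam1). Neither cluster 9 nor naive-like cluster 1 had a naive marker among its 10 leading genes.

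**Figure D1:**
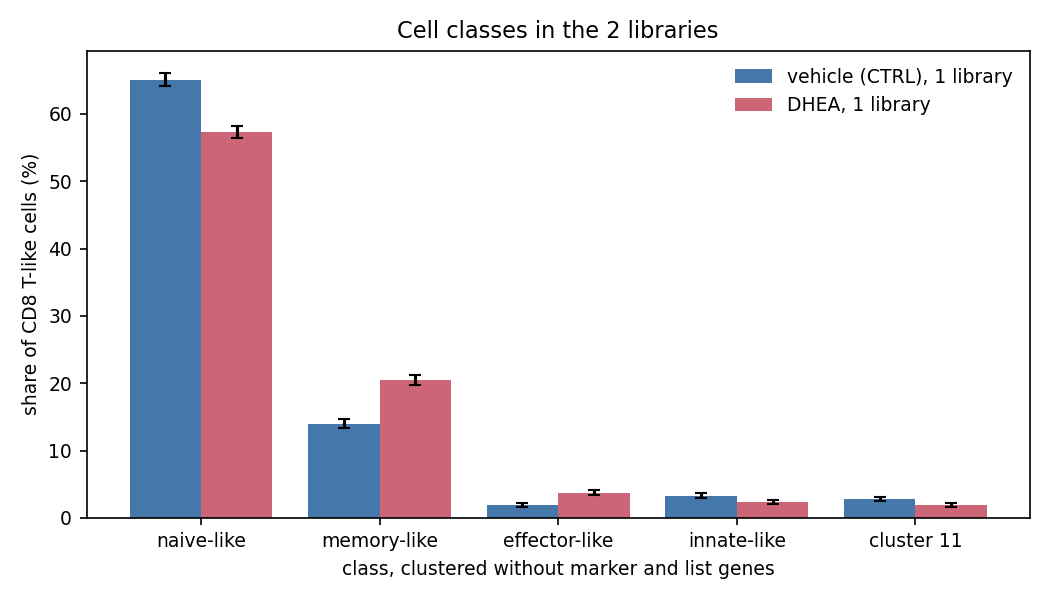
Percent of CD8 T-like cells in each class for the CTRL and DHEA libraries, clustered without marker genes; bars are shares and error bars exact 95% binomial intervals covering counting error only. Naive-like cells were 65.1% in CTRL and 57.3% in DHEA, and memory-like cells 13.996% and 20.5%.

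Of the genes higher in the DHEA library over all CD8 T-like cells, granzymes and other effector genes had the largest log2 ratios. Gzmb (ENSMUSG00000015437), a serine protease of cytotoxic granules, had 38 UMIs (0.762 CPM) in CTRL and 1151 (22.8 CPM) in DHEA, a log2 ratio of 4.90 (4.44 to 5.41). Gzma (ENSMUSG00000023132), another granule protease, stood at 2.97 CPM in CTRL and 57.7 in DHEA (4.28, 4.04 to 4.53). Gzmk had a log2 ratio of 3.41 (2.99 to 3.87). Klrg1, an inhibitory receptor of late effector cells, had 25 and 323 UMIs (3.67, 3.09 to 4.32). The sphingosine-1-phosphate receptor S1pr5 (2.13, 1.63 to 2.65), the fractalkine receptor Cx3cr1 (1.89, 1.52 to 2.27), the galectin Lgals3 (2.41, 2.05 to 2.78) and the calcium-binding S100a4 (2.11, 1.95 to 2.28) completed the 8 highest genes.

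Genes that were lower in the DHEA library included Eps8l1 (ENSMUSG00000006154), a relative of the actin regulator Eps8, with 20.1 CPM in CTRL and 1.61 in DHEA (log2 ratio -3.65, -3.99 to -3.32). The transcription factor Sox5 had 433 and 138 UMIs (-1.67, -1.95 to -1.39). Sag, the arrestin of photoreceptors, stood at 27.3 and 10.3 CPM (-1.41, -1.56 to -1.27). The other 5 of the 8 lowest were Casc1 (-1.42), Smagp (-1.26), Armh2 (-1.26), Gprc5b (-1.23) and the NADPH oxidase Nox1 (-1.23). The longest of 5 groups of genes by genomic span had a median log2 ratio of -0.16. Ratios of single genes here and below have no span median subtracted unless that is said. Eps8l1 was lower in the DHEA library in 11 of the 11 CD8 T-like clusters where it had at least 20 UMIs over both libraries. Counts of clusters given for other genes use the same minimum. Of 10528 genes, 187 were at least 1.5-fold higher and 168 at least 1.5-fold lower in the DHEA library, a rule of size and not a test. With cluster 13, left out of the class after its genes were seen, counted as CD8 T-like, the log2 ratio was 2.53 for Gzma, 3.99 for Gzmb and 1.13 for Lgals3. Without the effector-like cluster, and with cluster 13 again left out, the log2 ratio was 2.15 (1.52 to 2.84) for Gzmb. It was 1.02 (0.66 to 1.39) for Gzma, 2.15 (1.14 to 3.31) for Gzmk and 0.35 (0.01 to 0.69) for S100a4. It was 1.89 (-0.03 to 4.37) for Klrg1, with 3 and 11 UMIs, and 1.01 (-0.09 to 2.21) for S1pr5. Lgals3 (-0.28, -1.16 to 0.59) and Cx3cr1 (-0.32, -1.10 to 0.45) were then no longer higher in the DHEA library.

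**Figure D2:**
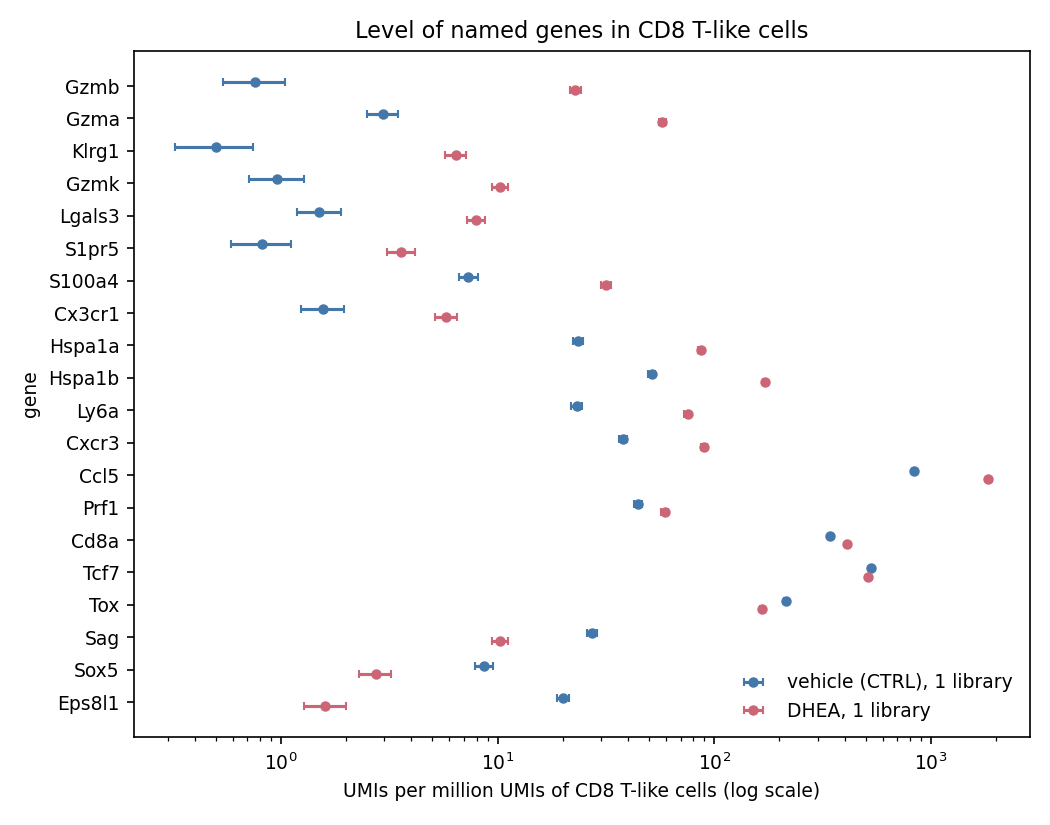
CPM (log axis) of named genes over all CD8 T-like cells of the CTRL and DHEA libraries; points are levels and error bars exact 95% Poisson intervals covering counting error only. Gzmb stood at 0.762 CPM in CTRL and 22.8 in DHEA, and Eps8l1 at 20.1 and 1.61.

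Gene groups of T cell effector function were higher in the DHEA library. Of the cytotoxic effector list, 21 of 21 measured members were higher, 18 of them by at least 1.5-fold, with a median log2 ratio of 1.31. These values include the effector-like cluster. Without it Cx3cr1 was no longer higher (-0.32), S100a4 stood at 0.35, and the intervals of Klrg1 and S1pr5 included no difference. Gzmb (2.15), Gzma (1.02) and Gzmk (2.15) stayed higher without it, while cluster 13 was also left out. Cluster 13 cells in the innate-like cluster made without marker genes held 336 CTRL and 39 DHEA UMIs of Gzma, Gzmb, Gzmk and Klrg1. The effector-like cluster was not left out with cluster 13 counted, so whether these genes stay higher then is not known. Ccl5, a chemokine stored by memory CD8 T cells, stood at 833 and 1845 CPM (1.15, 1.13 to 1.16) and was higher in 12 of 12 clusters. The effector cytokines Ifng and Tnf had log2 ratios of 0.94 and 0.73, the pore-forming protein gene Prf1 0.41 and the granule protein gene Nkg7 0.29. Of the memory list, 20 of 20 members were higher (median 0.61), among them the NK receptor gene Klrc1 (1.49), the death ligand gene Fasl (1.42), Gzmm (1.25) and the chemokine receptor gene Cxcr3 (1.24, at 38.0 and 89.7 CPM). The list of chemokines and homing receptors had 22 of 26 members higher (median 0.24), with Ccr2 at 1.56 and Ccl4 at 1.53. Cytokines and their receptors had 23 of 38 higher (median 0.15), with the cytokine-induced regulators Cish (0.98) and Socs3 (0.77) and the receptor chain Il12rb2 (0.76). Each of these 4 medians exceeded at least 99.9% of 10000 random lists matched on expression, a description of these libraries. The lists share members, such as Ccl5, Fasl, Cxcr3, Ifng and Tnf, so they are not separate results. The cytokine list had a median of 0.02 (percentile 50.5) within antigen-experienced cells and 0.06 (percentile 98.15) within naive-like cells. The cytokine list did not stand apart once each cell was thinned to 1000 UMIs (median -0.000678), or with genes of at least 1000 UMIs (0.05, percentile 91.0).

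The naive, inhibitory receptor and T cell receptor signalling lists had smaller medians in absolute size than the cytotoxic effector and memory lists. Single members, such as Klf2 (0.65) and Cd200 (-0.63), differed by more than the median of their list. The homing receptor gene Ccr7 had a log2 ratio of 0.21, the interleukin-7 receptor gene Il7r -0.03, and the naive-cell transcription factor gene Tcf7 -0.05. Klf2, a transcription factor of quiescent T cells, stood at 593 and 928 CPM (0.65) and was higher in 12 of 12 clusters. The naive list had 7 of 16 members higher (median -0.04, percentile 14.1), with Bach2 at -0.31, Foxp1 at -0.24 and Tsc1 at -0.24. The activation markers Cd44 and Cd69 had log2 ratios of 0.29 and 0.17. The list of inhibitory receptors had 2 of 8 members higher (median -0.10, percentile 15.4), with Cd200 at -0.63, Cd160 at 0.52, Cd101 at 0.33, and Tox, a transcription factor of exhausted T cells, at -0.36 (214 and 166 CPM). Pdcd1, which encodes PD-1, had 55 and 97 UMIs. T cell receptor signalling genes had 13 of 34 higher (median -0.07, percentile 5.54), with Plcg1 at -0.30 and Cblb at -0.25. The single values in this paragraph, that of Tox included, have no span median subtracted and so include any part of gene length.

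Heat shock genes were higher in the DHEA library in 13 of 14 cases (median 0.36, above all 10000 random lists). Hspa1b and Hspa1a, near-identical copies of the inducible chaperone HSP70 between which reads may be split, stood at 51.4 and 171 CPM (1.73, 1.67 to 1.80) and at 23.5 and 86.6 CPM (1.88, 1.79 to 1.97). Both were higher in 12 of 12 clusters, and the co-chaperones Dnajb1 (0.80) and Dnaja1 (0.65) were next. Immediate early genes, which handling of cells can induce, had 15 of 29 members higher (median 0.02, percentile 57.3), with Ier3 at 0.69, Atf3 at 0.53, Nr4a3 at -0.53 and Klf4 at -0.41.

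Cell cycle genes had 23 of 33 members higher (median 0.14, percentile 99.5), with Ccnb2 (0.72), Ube2c (0.71), H1f5 (0.50) and Birc5 (0.49), and Mki67 at 0.29. That median was 0.00 without the effector-like cluster and 0.03 (percentile 67.6) with genes of at least 1000 UMIs. Apoptosis and p53 genes had 14 of 20 higher (median 0.14, percentile 99.8), with the BH3-only genes Pmaip1 (0.59), Bbc3 (0.37) and Bid (0.22) and the survival gene Bcl2l1 (0.22). After thinning each cell to 1000 UMIs, the cell cycle median was at percentile 81.7 and the apoptosis median at 89.3; with the median of genes of like genomic span subtracted, the apoptosis median was 0.07 (percentile 94.9).

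Among genes of energy metabolism, nuclear genes of oxidative phosphorylation were higher in 63 of 75 cases (median 0.10, above all random lists), with Cox5a at 0.31, Cox5b at 0.30 and Cycs at 0.29, while the complex I gene Ndufs8 stood apart at -1.12 (49.7 and 22.8 CPM). With the median of genes of like genomic span subtracted, that list had a median of 0.04 (percentile 93.0). Mitochondrially encoded genes were lower in 13 of 13 cases (median -0.30, below all random lists), with mt-Atp8 at -0.68, mt-Nd3 and mt-Nd2 at -0.49 and mt-Nd5 at -0.46. Glycolysis genes had 15 of 21 higher (median 0.13, percentile 99.7), with Pgam1 (0.44), Hk2 (0.40) and Tpi1 (0.27), and the hypoxia factor Hif1a at -0.29. Fatty acid oxidation genes had a median of -0.03 (percentile 42.2, 8 of 21 higher), with Cpt1a, the carnitine acyltransferase that admits fatty acids to mitochondria, at -0.76 (26.3 and 15.5 CPM), Acsl1 at -0.22 and Etfb at 0.21. Cholesterol synthesis genes had a median of 0.08 (percentile 90.6, 15 of 21 higher), with Idi1 at 0.60, Mvd at 0.39, Cyp51 at 0.32 and Srebf2 at -0.30. Antioxidant genes had a median of 0.05 (percentile 85.2, 12 of 19 higher), with Prdx4 at -0.38, Gpx1 at 0.32, Prdx1 at 0.30 and Prdx3 at 0.27.

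Over the list of steroid hormone receptors and enzymes the median log2 ratio was 0.00 (percentile 59.5, 10 of 20 higher), with the estrogen receptor gene Esr1 at -0.79 (11.8 and 6.84 CPM), the cholesterol transporter gene Star at -0.79 and Hsd17b7 at 0.59. The glucocorticoid receptor gene Nr3c1 differed by 0.02 and its target Tsc22d3 by -0.12. The glucocorticoid response list had a median of -0.03 (percentile 33.6, 8 of 19 higher), with Klf9 at -0.80, Sgk1 at 0.58, Txnip at -0.49 and Per1 at -0.36.

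Type I interferon response genes were lower as a list in the DHEA library (median -0.11, percentile 0.52, 15 of 42 higher), with members on both sides: Usp18 at 0.65, Ifit2 at 0.60, Rnf213 at -0.57 and Dhx58 at -0.50. After thinning, the median was -0.09 at percentile 8.15. Within naive-like cells this list had a median of -0.04 (percentile 47.0) and within antigen-experienced cells 0.03 (percentile 63.2). Interferon gamma response genes had a median of -0.05 (percentile 21.0, 11 of 25 higher), with Socs1 at 0.58, Ifi47 at 0.54, Iigp1 at 0.37 and Gbp6 at -0.35. MHC class I genes had a median of 0.06 (percentile 84.4, 12 of 16 higher), with H2-Q6 (0.32), H2-M3 (0.28), H2-Q7 (0.26) and H2-K1 (0.24), a family whose copies can share reads. Genes of mTOR, MYC and amino acid uptake had a median of 0.06 (percentile 91.3, 14 of 22 higher), with Mtor at -0.29, Myc at 0.28, Rptor at -0.22 and Slc1a5 at 0.21. Ribosomal protein genes had a median of 0.04 (percentile 59.2, 50 of 81 higher), with Rps29 at -0.45, Rpl7l1 and Rps27l at 0.41 and Rps28 at -0.29; with span medians subtracted the list median was -0.07, below all random lists.

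Few genes of the lists for other cell types were measured. The immunoglobulin and B cell list had 3 measured members with a median of 0.10 (percentile 75.5): Ighm at 0.12, Cd79b at 0.10 and Ighd at -0.15. Over all kept cells Ighm had UMIs in 6023 CTRL and 7012 DHEA cells, at 246 and 266 CPM. The myeloid list had 4, Cd68 at -0.56, Fcer1g at -0.35, Lst1 at -0.23 and Cst3 at 0.04, with a median of -0.29 (percentile 1.58) that was 0.04 when genes with at least 50 UMIs were measured. The erythroid list had Car2 at -0.34 and Bpgm at -0.04, and the list of X inactivation and Y-linked genes had Tsix at -0.28 and Xist at -0.04.

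**Figure D3:**
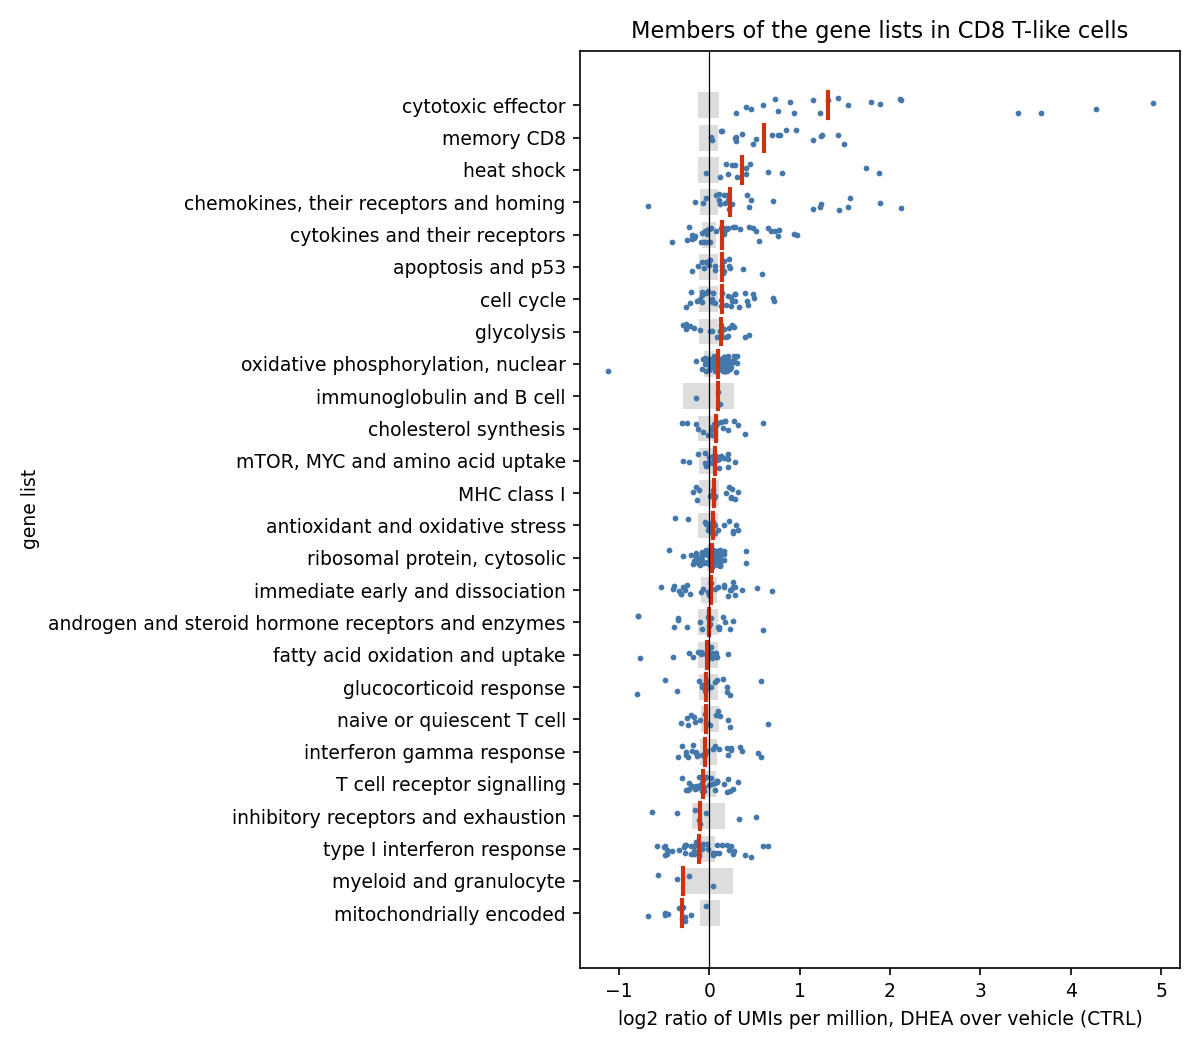
Log2 ratio of DHEA over CTRL in CD8 T-like cells for the members of each gene list (points), the list median (red line) and the central 95% of medians of 10000 random lists matched on expression (grey bar). The cytotoxic effector median of 1.31 and the memory median of 0.61 lie above that range, and the mitochondrially encoded median of -0.30 lies below it.

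In cells thinned to 1000 UMIs each, a Ccl5 UMI was found in 17.4% of CD8 T-like cells in CTRL and 34.6% in DHEA. In naive-like cells, which should lack most effector transcripts, these shares were 3.93% and 13.7%. Gzmb was found in 0.0909% and 1.23% of CD8 T-like cells, against 0.0201% and 0.140% of naive-like cells. Gzma was found in 0.182% and 1.58%, against 0.120% and 0.360% (6 and 18 cells). Gzmk was found in 0.114% and 0.823%, against 0 of 4982 naive-like cells in CTRL, for which 3 cells as the limit allow a share of cells with a UMI of up to 0.0602%, and 0.120% in DHEA. The corresponding shares for Prf1 were 4.29% and 6.21%, against 3.41% and 4.76%, and for Ifng 0.648% and 1.28%, against 0.181% and 0.200%. Tnf was found in 2.22% and 3.38%, against 1.43% and 2.16%. Thinning left out 6 CTRL and 206 DHEA cells, 1 and 121 of them naive-like; median depths were 5627 and 4434 UMIs for CD8 T-like and 5263 and 3227 for naive-like cells. Without thinning the CD8 T-like shares were 30.9% and 50.2% for Ccl5, 0.318% and 2.55% for Gzmb, 0.874% and 3.12% for Gzma, 0.375% and 1.99% for Gzmk, 20.4% and 21.5% for Prf1, 2.96% and 4.37% for Ifng, and 8.82% and 11.2% for Tnf.

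Within naive-like cells the chaperone genes led. Hspa1b stood at 17.3 CPM in CTRL and 128 in DHEA (log2 ratio 2.89, 2.74 to 3.04) and Hspa1a at 8.79 and 62.7 (2.84, 2.63 to 3.05). Cluster 2, which these genes lead, was outside the naive-like class; with it counted in, their log2 ratios were 1.73 and 1.84. Ly6a, the interferon-inducible surface protein Sca-1, stood at 12.9 and 61.0 CPM (2.24, 2.06 to 2.42). Ccl5 (1.95, 1.86 to 2.04) and Cxcr3 (1.85, 1.59 to 2.11) followed. Ccl5 stood at 55.5 and 214 CPM, against 2317 and 4246 in antigen-experienced cells, and Cxcr3 at 6.82 and 24.5, against 119 and 192. Free RNA and misassigned cells were not separated from expression for Ly6a, Ccl5 or Cxcr3, so no difference in naive-like cells themselves is read from them. The 5 lowest genes were Eps8l1 (-3.74, -4.34 to -3.20), Sag (-1.68), Sox5 (-1.38), Fhit (-1.19) and Ndufs8 (-1.16). Of 9079 genes, 84 were at least 1.5-fold higher and 111 at least 1.5-fold lower.

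In naive-like cells the heat shock list was higher in 13 of 13 measured members (median 0.35). The cytotoxic effector list was higher in 9 of 10 (0.54) and the memory list in 12 of 14 (0.25), but these cells also serve as the background for such transcripts, so neither value is read as a difference in naive-like cells themselves. Immediate early genes had 17 of 26 members higher (median 0.12, percentile 99.9), and the interferon gamma list had a median of 0.09 (percentile 98.9) with Iigp1 at 1.03. Mitochondrially encoded genes were lower in 13 of 13, and T cell receptor signalling genes had a median of -0.15 (percentile 0.15, 10 of 34 higher). The medians of genes of like span were not subtracted within naive-like cells. The part of gene length in these list values, and in the ratios of single genes, is therefore not known. Of 24 lists, the cytotoxic effector and memory lists included, 13 lay above and 2 below the central 95% of random lists. Klf2 had a log2 ratio of 0.74, Ccr7 0.39, Tox -0.51 and Cpt1a -0.92. The largest cluster of the class was cluster 0 in CTRL, with 2168 of 4983 cells, and cluster 3, which has fewer UMIs per cell, in DHEA, with 1797 of 5123 cells. Cluster 1 held 1629 and 1533.

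Within antigen-experienced cells the granzymes again led. Gzmb had 19 UMIs (1.85 CPM) in CTRL and 1071 (66.9 CPM) in DHEA, a log2 ratio of 5.17 (4.52 to 5.91). Gzma stood at 8.49 and 174 CPM (4.36, 4.05 to 4.68). Klrg1 (3.20, 2.57 to 3.89), Gzmk (2.85, 2.40 to 3.33) and Lgals3 (2.29, 1.87 to 2.75) followed. The 5 lowest were Eps8l1 (-3.54, -4.19 to -2.95), Sag (-1.31), the neuronal gene Auts2 (-1.24), the histone gene H3c3 (-1.07) and the DNA repair gene Rad51b (-1.07). No span medians were subtracted in these cells, so the part of gene length in these ratios is not known. Of 8283 genes, 138 were at least 1.5-fold higher and 98 at least 1.5-fold lower, the latter 59 without the effector-like cluster. Without that cluster Gzmb had 6 and 30 UMIs (log2 ratio 1.71, 0.42 to 3.27) and Gzma 33 and 63 (0.32, -0.31 to 0.98).

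The cytotoxic effector list was higher in 21 of 21 members in these cells (median 1.37), the effector-like cluster included. Homing genes were higher in 25 of 26 cases (0.32) and nuclear oxidative phosphorylation genes in 70 of 75 (0.14). Span medians were subtracted only over all CD8 T-like cells, so the part of gene length in these list values is not known. Memory genes had 17 of 20 higher (0.49) and heat shock genes 14 of 14 (0.24). Cell cycle genes were lower in 21 of 29 (median -0.26, below all random lists), with Mki67 at -0.34 (-0.60 to -0.07). Over all CD8 T-like cells that median was 0.14. The effector-like cluster, which proliferation genes also lead, is part of these cells. In it 22.8% of CTRL and 65.0% of DHEA cells had a UMI of Gzma, Gzmb, Gzmk or Klrg1. The list was not measured here without that cluster, so no difference in cycling within a single kind of cell is read from it. Mitochondrially encoded genes were lower in 12 of 13 (-0.25), and ribosomal protein genes had a median of -0.04 (percentile 0.15). Of 25 lists, 7 lay above and 3 below the central 95% of random lists. Cluster 4 was the largest of the class in both libraries, with 844 CTRL and 1362 DHEA cells, and cluster 5 had 434 CTRL and 1207 DHEA cells, with median depths of 5880.5 and 2681 UMIs.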

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

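The tests of free RNA, handling, the mix of cell states, nuclear RNA and DHEA treatment were chosen only after the result was seen, and the tests of CD8 co-detection, gene length and depth were set before.

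Gzma, Gzmb, Gzmk and Klrg1 UMIs were more frequent in the DHEA library. In a clustering made without these genes, an effector-like cluster with 4.20% of the DHEA library's CD8 T-like UMIs held 85.3% of the UMIs of these 4 genes, which argues against free RNA spread over all droplets. Of the 303 DHEA cells with a Gzmb UMI, 268 (88.4%, 84.3 to 91.8) also had UMIs of CD8 and CD3 genes, which argues against NK or other cells without CD8 carried through the bead isolation; in CTRL it was 29 of 43 (67.4%). In CTRL the largest part of the 4 genes' UMIs, 359 in 16 cells, lay in the innate-like cluster of that clustering, 336 of them in 8 cells of cluster 13, which the CD8 T-like sums leave out. DHEA treatment may underlie the difference, but it cannot be told apart from other differences between the animals or preparations, since each group has 1 library.

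Hspa1a and Hspa1b were higher in the DHEA library. After the median of genes of like span was subtracted, their log2 ratios were 1.76 and 1.61. Median log2 ratios over 5 span groups ran only from 0.11 to -0.16, so the subtraction could change ratios of this size little. The average trend is too small to give such ratios, which argues against the gene length trend as the cause. Handling of the spleen or the cells could raise chaperone genes; the immediate early list had a median of 0.018 with 26 of 29 members below 0.3, short of the 90% set as evidence against it, so it stays open. DHEA treatment cannot be told apart from such differences with 1 library per group.

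Genes of long genomic span were lower in the DHEA library: the median log2 ratio was 0.11, 0.07, 0.01, -0.07 and -0.16 over 5 equal groups of genes from the shortest to the longest. Among cells of 3000 to 6000 UMIs the rank correlation across genes, which are not independent replicates, was -0.47, which argues against fewer UMIs per cell as the whole cause. Within single clusters it lay between -0.57 and -0.34 in 11 of 12 and was 0.039 in cluster 11, so a different mix of cell states could not be excluded by the bound of -0.2 in every cluster. For less nuclear RNA, the nuclear transcripts went both ways (Malat1 -0.39, Neat1 0.17, median -0.0061), and this cannot be told apart from the other open explanation because 4 transcripts in 1 library per group do not decide it.

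Cluster 6, outside the comparisons of CD8 T-like cells, held 5.03% of DHEA and 3.08% of CTRL cells. Barcodes with at least 10% mitochondrial UMIs, which were left out, made up 3.77% (3.44 to 4.12) of the DHEA and 3.002% (2.67 to 3.36) of the CTRL library.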

How the results depend on the processing

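The alternatives that counted cluster 6, cluster 13 or cluster 2 in a class, left out marker genes, the effector-like cluster or high doublet scores, or subtracted span medians were chosen only after the result was seen. Of 1984 values of named genes under an alternative, 1808 stayed within their counting interval, 176 moved and 0 reversed. Reversal was counted only for genes at least 1.5-fold apart, so smaller ratios could change sign without being counted. The UMI minima of 50 and 1000 leave a named gene's ratio unchanged by construction. Ignoring the doublet call repeats the main result, since no doublets were removed. These settings are no evidence of stability for named genes. Of 386 list medians 374 kept their place inside or outside the central 95% of random lists, 10 did not and 2 reversed, counted only for lists outside that range. Of 32 shares of cells with a UMI, 9 stayed within their interval, 20 moved and 3 reversed, and of 157 class shares and counts of genes or lists 119 stayed and 38 moved. The cytokine list median was -0.000678 after thinning to 1000 UMIs, and the myeloid list median was 0.045 with genes of at least 50 UMIs, where more members entered. No paired analysis was possible because each group has 1 library.

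The CD8 T-like share was 98.2% in CTRL and 96.9% in DHEA under a 5% mitochondrial limit, 93.7% and 91.2% by the gate, 98.7% and 98.4% with cluster 6 counted, 96.8% and 94.8% with cluster 13 counted, and 94.0% in DHEA without centring per library. The naive-like difference was -7.36 points under the 5% limit, -8.12 with at least 500 genes, -3.51 at resolution 0.5, -7.75 at resolution 1.5, -13.5 without centring and -7.79 without marker genes. The memory-like difference was 7.94 with at least 500 genes, 3.27 at resolution 0.5, 12.7 without centring and 6.50 without marker genes. For antigen-experienced cells these 4 values were 10.1, 5.58, 15.4 and 8.28. Every alternative for these 3 differences had the same direction; the cause of the size was not tested.

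Genes at least 1.5-fold higher and lower in CD8 T-like cells numbered 410 and 515 with at least 50 UMIs and 73 and 42 with at least 1000, as more or fewer genes entered. They numbered 112 and 95 of 7588 genes after thinning, of which 61 and 33 were shared with the 187 and 168 of the unthinned sums; the cause was not tested. At 2-fold there were 46 and 25. TMM scaling gave 208 and 141. In antigen-experienced cells without the effector-like cluster 59 genes were lower. Lists below the central 95% numbered 1 after thinning. Without thinning, the shares of cells with a UMI were lower in the DHEA library by values of -3.70 points for Nkg7, -3.60 for Ccr7 and -5.46 for Cd69, against their CPM, and no order is read from them: DHEA cells had fewer UMIs. That depth limits genes with few UMIs, such as Pdcd1 with 55 and 97.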

Other observations

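The looks at markers of other cell types over all kept cells and at T cell receptor segments were chosen only after the result was seen. Over all kept cells, single cells held most UMIs of some myeloid genes. Lyz2, the lysozyme of macrophages and neutrophils, had 939 UMIs in CTRL, 536 of them in 1 cell, and 61 in DHEA. The neutrophil calprotectin genes S100a9 and S100a8 had 1 UMI each in CTRL and 258 and 205 in DHEA, 253 and 201 of them in 1 cell. NK receptor genes did not move together: Klre1 had 747 and 1728 UMIs (log2 ratio 1.18) and Klra8 64 and 172 (1.39), while Ncr1 had 52 and 30, and the adaptor genes Tyrobp and Fcer1g had log2 ratios of -0.56 and -0.52. Cd4 had 7 and 4 UMIs.

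Among the UMIs of T cell receptor beta V segments in effector-like cells, Trbv12-2 was the most frequent, with 7 of 45 UMIs in CTRL (15.6%, 6.49 to 29.5) and 17 of 79 in DHEA (21.5%, 13.1 to 32.2). Its share of such UMIs was 13.3% in CTRL and 16.3% in DHEA in naive-like cells, and 19.8% and 16.9% in memory-like cells. Eps8l1 was lower in the DHEA library in each of the 11 CD8 T-like clusters where it had at least 20 UMIs. Its log2 ratios there lay between -4.58 and -2.60.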
